A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

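Chromatin immunoprecipitation on tiling arrays (ChIP-chip) was used to map Sas3, the catalytic subunit of the NuA3 histone acetyltransferase complex, along the genome of the budding yeast Saccharomyces cerevisiae. Per the labels' protocols, cells growing exponentially in rich medium (YPD) to an optical density of 0.5 to 0.8 were fixed for 30 min in 1% formaldehyde, chromatin was sonicated to an average of 400 bp, and DNA was recovered with 2 µg of an anti-HA antibody. The recovered DNA was amplified by ligation-mediated PCR to an average of 150 bp, per the labels' protocols, and 2000 ng of each sample was labelled. The Cy5 channel of each array held the precipitate from strain BQS1217, in which Sas3 carries an HA tag, and the Cy3 channel held the precipitate with the same antibody from the untagged parent BY4742. The labels describe 2 biological replicates, each on its own array, and both arrays fall in the single group Sas3-HA over untagged. Dyes were not swapped, so a dye effect and a sample effect cannot be told apart. The arrays were scanned on 1 day. Whether the Cy3 DNA of both arrays came from separate cultures is not given in the sources used here.

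Each Agilent array held 243504 spots, of which 5596 were control spots and 237908 were genome probes with a median length of 60 bases and a median midpoint spacing of 44 bp. The deposited log10 ratio is that of Cy5 over Cy3, per the file headers, made from processed signals after background subtraction, spatial and multiplicative detrending and linear dye normalization. The deposited intensity columns hold, per the file headers, mean, background, background-subtracted and processed signals of each channel. The headers name Feature Extraction 9.5.3.1, whereas the submitters' processing notes name version 10.10.1.1. The authors' value table of the series held the same log10 ratios at all 243504 features of each array, not centred, with medians of 0.0667 and -0.140 over the arrays. Deposited spot flags and surrogate values are of no fixed unit and were used as given by the authors.

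For the results below, log10 ratios were turned to log2, control spots and spots flagged as non-uniform or population outliers were left out (26 and 126 genome probes), and each array was centred on its median probe, which had a log2 ratio of 0.22 on array 1 and -0.47 on array 2 as deposited. A value of 0 is therefore the median probe of an array, not absence of Sas3. No loess or quantile normalization was applied. No genome sequence and no probe sequence were used, so probes were placed by the coordinates printed with them, whose genome build is not given in the sources used here. The start of each reading frame was taken from the offset printed with its probes, and its end from the last probe inside it plus 25 bp, so ends are approximate. Of 5585 reading frames used, 5566 were matched by systematic name to symbols of a reference gene table, from which no coordinate was taken. A further 114 reading frames had no probe inside.

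Window means were taken over probes for the first 500 bp of each reading frame (5' window), the 500 bp upstream of the start codon (promoter window) and the last 500 bp (3' window), with at least 3 probes. The untagged strain's DNA is in the other channel of each array, so each mean log2 ratio was tested against 0 with limma (lmFit with an intercept alone, eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Differences of Cy3 between the arrays enter the spread of the ratios, but if both arrays held the same control DNA, the spread between control samples is left out. An exact sign-flip test of 2 arrays cannot give a two-sided p below 0.5, so the limma p-values rest on the variance shared across genes. Differences between 5' and 3' windows were taken for reading frames of at least 1000 bp. The 33 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, and with an estimated correlation as an alternative. Feature classes outside reading frames were tested by a circular-shift permutation with 1000 shifts of the probe values along the genome, whose smallest p is 0.001. Intergenic intervals were classed by the direction of the neighbouring genes and by the tRNA, snoRNA or snRNA genes that the reference's gene order places between the same neighbours. Subtelomeres were the 20000 bp next to the outermost probes. Enriched regions were runs of at least 5 probes, with gaps of at most 300 bp, that passed 2 robust SD on both arrays. The robust SD of an array was taken from its values below the centre, and the same cut-offs served for depleted runs.

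Named genes followed a rule fixed before the data were examined. For the 5' window these were the 12 largest positive and 8 largest negative mean ratios among genes with an adjusted p under 0.05 and the same sign on both arrays. For 5' minus 3' the numbers were 6 and 4, and for the promoter and 3' windows 4 and 2. Where fewer passed, places were filled by the largest means of the same sign on both arrays. A gene whose window overlapped that of a gene already taken by more than 50% was skipped. SAS3, the other NuA3 subunits and the marker loci HIS3, LEU2, LYS2 and URA3 were always included, as were the 2 highest members and the lowest member of each list described and the 5 enriched regions of largest mean, of which 1 was found. Lists given only by their counts name no member. The part of the rule that skips genes whose probes are not unique could not be applied without probe sequences.

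Signal over background limits the precision of arrays, as does their number. Over 99.5% of probes were well above background in each channel of each array. The median background-subtracted Cy5 signal was 7588 on array 1 and 563.2 on array 2, and the median Cy3 signal was 1108 and 742.1. The SD of the log2 ratio over probes was 1.64 and 2.63. The procedure was tested on simulated data with a single SD for all genes, set from the median spread between the arrays. Of 50 genes changed by a log2 ratio of 2 among 5480, the 5' window test recovered 4%. Of those changed by 4 it recovered 80%, and of those changed by 6 it recovered 100%, while it also called 6 unchanged genes. For 5' minus 3' differences over 3378 genes the shares were 2%, 48% and 96%, and 9 unchanged genes were called. The simulated arrays were independent, with a mean of 0 for unchanged genes. The measured 5' windows had SDs over genes of 1.30 and 2.18, means of -0.003 and 0.72, and r = 0.49 between arrays. Recovery and false calls in the measured data may therefore differ from these shares.

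Alternatives covered normexp background correction (offset 50), loess (span 0.3), centring, the series value table, dim and flagged probes, window length and summary, the variance model, the genes used, list tests, region thresholds and each array alone. A fitted slope on the control channel, equal scaling of the arrays, a circular-shift test of the mean within-gene differences and a permutation of interval labels were added after seeing the data. Correction for probe GC content, placement of probes with several matches and windows around non-coding features (with 100 or 250 bp on each side) were not run, and rDNA, Ty and LTR elements, centromeres and replication origins were not analysed here. Computations used R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.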

Results

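Occupancy of HA-tagged Sas3 was measured on 2 tiling arrays, each comparing the anti-HA precipitate of the tagged strain in Cy5 with that of the untagged strain in Cy3. Values are mean log2 ratios of Cy5 over Cy3, centred on each array's median probe, and errors are the SD of 2 arrays unless stated otherwise. Over 99.5% of the 237908 genome probes were well above background in each channel.

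The strain's marker loci were examined first, since genes deleted from the parent have no target in either channel unless the tagging cassette restored one. BY4742 lacks LEU2, LYS2 and URA3, which encode enzymes of leucine, lysine and uracil synthesis, and carries a partial deletion of HIS3, a gene of histidine synthesis. Over the LEU2 reading frame (chromosome 3, from 91322), the geometric mean Cy5 signal was 79.0 on array 1 and 38.5 on array 2, and over LYS2 (chromosome 2, ending at 473881) it was 56.2 and 14.7. URA3 (chromosome 5, from 116166) gave 362.9 and 21.1 in Cy5 and 35.1 and 13.7 in Cy3, with a log2 ratio of 1.05 ± 0.20 (SD, n = 2). LEU2 had a log2 ratio of 0.12 ± 1.56 and LYS2 one of 0.17 ± 1.15, each below 0 on array 1 and above 0 on array 2. In Cy5, 91.7% and 95.8% of LEU2 probes, 81.1% and 72.2% of LYS2 probes and 93.3% and 86.7% of URA3 probes were still called well above background on arrays 1 and 2, so that call alone does not mark target DNA. Over SAS3 (chromosome 2, ending at 121836), the Cy5 signal was 5316 and 630.7. HIS3 (chromosome 15, from 721945) had a Cy5 signal of 4067 and 1319 and a log2 ratio of -1.19 ± 1.08. The HA tag is not seen by the probes, so the SAS3 locus does not check the tag itself. The SAS3 reading frame had a log2 ratio of 0.62 ± 1.07 (SD, n = 2), and its 5' window one of -0.69 ± 0.96 (limma adjusted p = 0.752). Among the other NuA3 subunits, 5' window means were 0.90 ± 0.05 for NTO1, 0.76 ± 1.47 for PDP3, -0.28 ± 0.69 for EAF6, -1.01 ± 1.77 for YNG1 and -2.14 ± 0.70 for TAF14. None of the 6 subunits passed the limma test, and the lowest adjusted p was 0.222 for TAF14.

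How far the replicates shared a profile was asked next. Across the 5' windows of 5480 genes, the log2 ratios of both arrays correlated with a Pearson r of 0.49 and a Spearman rho of 0.47. Genes are not independent replicates, and these are correlations across genes. With the Cy3 signals exchanged between the arrays, the ratios correlated with r = 0.27. That exchange keeps both Cy3 profiles in the ratios, so 0.27 is not the agreement left without a shared control profile. Whether both arrays held the same control DNA is not given in the sources used here, and shared control DNA would add to the agreement of the ratios. The untagged Cy3 signals correlated with r = 0.94 between arrays, and the Sas3-HA Cy5 signals with r = 0.22. On each array the ratio was negatively correlated with the control signal of the same windows, with r = -0.75 on array 1 and -0.46 on array 2, a sign that a ratio over the same Cy3 values favours by construction. Promoter and 3' windows had ratio correlations of 0.47 and 0.47, Cy3 correlations of 0.94 and 0.95, and Cy5 correlations of 0.24 and 0.23. The ratios of 66.5% of the genes had the same sign on both arrays in the 5' window.

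**Figure D1:**
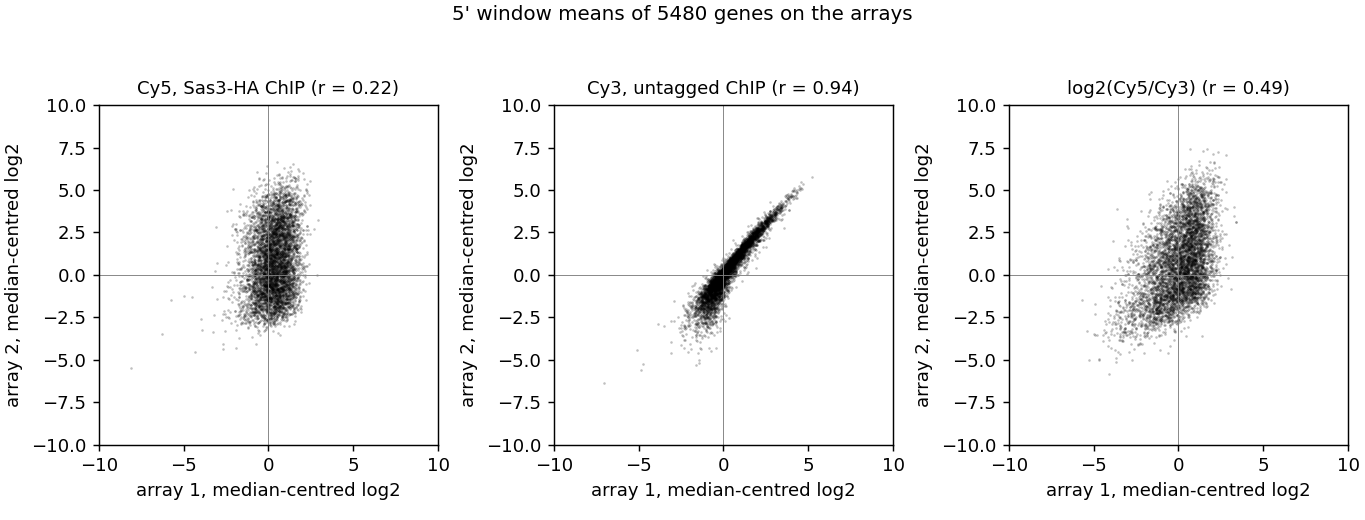
Median-centred log2 5' window means of each gene on array 1 (x axis) and array 2 (y axis), for Cy5, Cy3 and their log2 ratio, with 1 point per gene (5480 genes). The Cy3 points lie along a line (r = 0.94), and the Cy5 points spread widely (r = 0.22).

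Which genes had a higher or lower ratio at their starts than the median probe was tested over 5480 genes. The average 5' window was not at 0 itself: its mean was -0.003 on array 1 and 0.72 on array 2, or 0.36 over both. The largest ratios lay in the 5' windows of DMA2, which encodes a ubiquitin ligase of the spindle position checkpoint, PUP2, an alpha subunit of the proteasome core, RCR1, a membrane protein linked to chitin deposition, and UTP15, a factor of small-subunit ribosome assembly. Their mean log2 ratios were 4.95 ± 3.00, 4.78 ± 3.50, 4.58 ± 3.61 and 4.57 ± 4.05 (SD, n = 2). The DMA2 (YNL116W) window spans 408337 to 408836 on chromosome 14, and that of PUP2 (YGR253C) spans 998644 to 999143 on chromosome 7. GYP1, a GTPase-activating protein of vesicle traffic, FAP1, YRB2, a Ran-binding protein of nuclear export, COX19, a cytochrome oxidase assembly factor, and BOR1, a borate exporter, had means from 4.27 to 4.38. RAD14, a damage recognition factor of nucleotide excision repair, reached 4.23 ± 2.00, JEN1, the lactate and pyruvate permease, 4.21 ± 2.92, and PEX5, the peroxisomal import receptor, 4.09 ± 2.96. In all 12 genes array 2 gave the higher ratio, as in DMA2 with 2.83 on array 1 and 7.07 on array 2.

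The most negative ratios lay in MIC10, which encodes a core subunit of the mitochondrial MICOS complex, with -5.12 ± 0.19, and in RPA14, a subunit of RNA polymerase I, with -4.97 ± 1.25. SSK1, the response regulator of the osmosensing phosphorelay, had -4.83 ± 0.22 and LSO1 had -4.82 ± 0.16. CDC26, a subunit of the anaphase-promoting complex, MCM5, a subunit of the replicative helicase, HSV2, a phosphoinositide-binding protein, and SAN1, a nuclear ubiquitin ligase for misfolded proteins, ranged from -4.38 to -4.24. The MIC10 (YCL057C-A) window spans 24025 to 24325 on chromosome 3, and the SSK1 (YLR006C) window 163393 to 163892 on chromosome 12. In limma, 61 genes passed an adjusted p of 0.05, of which 36 were higher and 25 lower, and adjusted p ranged from 0.0162 to 0.0402 over the 20 named genes. The count rests on the settings: it was 376 without centring, 21 with flagged spots kept, 2 with a fitted slope on the control, and 0 without moderation of the variance. The split moved too, with 224 higher and 152 lower without centring, but 8 and 13 with flagged spots kept. Without genes near chromosome ends it was 19 higher and 20 lower. With trend and robust variance, 0 genes were higher and 307 lower. A call need not be a gain or loss of Sas3-HA. Across 5' windows Cy3 correlated with r = 0.94 between arrays and Cy5 with r = 0.22. A low or high Cy3 signal on both arrays can therefore give ratios of the same sign. The same limit holds for the other windows and differences below.

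**Figure D2:**
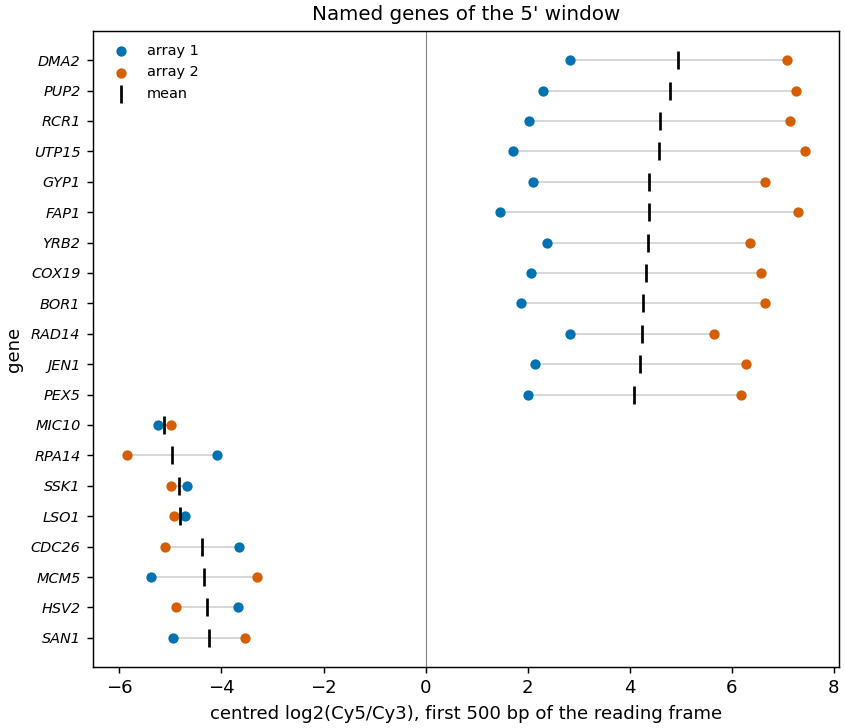
Centred log2 ratio of the 20 named genes in the first 500 bp of the reading frame (x axis), with array 1, array 2 and their mean as separate marks. The upper 12 genes have means from 4.09 to 4.95, and the lower 8 from -5.12 to -4.24.

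Signal upstream of genes was tested in 5553 promoter windows. The largest means, 4.38 ± 3.31 upstream of MSS4, a phosphoinositide kinase, 4.10 ± 2.73 upstream of SAM35, a mitochondrial outer membrane assembly factor, 4.02 ± 2.87 upstream of LHP1, the yeast La protein, and 3.84 ± 3.04 upstream of MOG1, a Ran-binding protein, missed the threshold with a limma adjusted p of 0.344. The inositol transporter gene ITR1 and the iron permease gene FTR1 had -4.93 ± 0.64 and -4.70 ± 0.44 and also missed it (adjusted p = 0.321). By limma 0 promoter windows passed, while 776 had an unadjusted p under 0.05. Under loess 242 windows passed (97 higher and 145 lower) and without centring 313 (146 and 167). With trend and robust variance 344 passed, 0 higher and 344 lower.

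Toward the ends of genes, APM2, which encodes a clathrin adaptor subunit, and YND1, a Golgi apyrase, had 3' window means of 4.49 ± 2.90 and 4.37 ± 2.98. COX19, whose short reading frame gives the same window at both ends, had 4.32 ± 3.18, and BUD23, a ribosomal RNA methyltransferase, 4.15 ± 2.59. ZIM17, a mitochondrial chaperone factor, and RGC1, a regulator of the glycerol channel, had -5.13 ± 0.86 and -5.12 ± 1.17. Of 5475 windows tested with limma, 89 were higher and 74 lower at an adjusted p of 0.05. The split turned to 112 higher and 149 lower under loess and to 117 and 168 with the arrays scaled to equal SD. With the fitted slope on the control 0 passed, and with trend and robust variance 0 were higher and 412 lower.

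Whether the signal lay nearer the start than the end of genes was asked in 3378 reading frames of at least 1000 bp. RGC1 was 7.29 ± 0.28 higher on the log2 scale in its 5' than in its 3' window. SRP68, a subunit of the signal recognition particle, TIM44, a mitochondrial import motor subunit, YDR341C, the arginyl-tRNA synthetase gene, GYP1 and RIM8, an arrestin-related protein of pH signalling, followed with differences from 6.47 to 6.89. MDM38 and MDM10, which encode mitochondrial membrane proteins, UBP15, a ubiquitin protease, and DAL5, the allantoate permease, had differences from -6.14 to -5.89. The mean over genes was 0.24 on array 1 and 0.27 on array 2, or 0.26 ± 0.02 (SD, n = 2). The difference was above 0 in 56.2% of genes on array 1 and 52.6% on array 2, with SDs over genes of 1.78 and 2.97. A circular-shift permutation, chosen after the data were examined, gave central 95% ranges of -0.06 to 0.06 on array 1 and -0.09 to 0.09 on array 2, and each array's mean reached the smallest permutation p of 0.001 (adjusted p = 0.0013 over 16 tests). In Cy5 alone the means were 0.20 and 0.19, and in Cy3 -0.04 and -0.08. By limma 243 genes passed, with 163 higher and 80 lower at the 5' end. Under loess, under normexp, with trend and robust variance and with the fitted slope 0 passed. The mean over genes stayed between 0.23 and 0.32 in every setting run. The variance model and the series value table cannot move that mean, and single arrays must lie on either side of it.

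Signal in the first 500 bp of reading frames exceeded that of the upstream 500 bp by a mean of 0.31 on array 1 and 0.11 on array 2, or 0.21 ± 0.14 (SD, n = 2), over 5471 genes. By limma 181 genes were higher and 101 lower in the 5' window than upstream. Both channels rose from promoter to reading frame, by 0.80 and 0.69 in Cy5 and by 0.49 and 0.58 in Cy3. In the circular-shift permutation, chosen after the data were examined, the plain mean difference had a p of 0.001 on array 1 and 0.003 on array 2. After loess the mean difference was 0.42 on array 1 (permutation p = 0.001) but -0.03 on array 2 (permutation p = 0.466). With median summaries 20 genes passed, with the fitted slope on the control 3, and with trend and robust variance 0.

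Along reading frames of at least 1000 bp, the mean ratio of both arrays was highest from 300 to 349 bp after the start codon, at 0.43, and lowest in the upstream bin from -350 to -301 bp, at 0.09. The highest bin had 0.03 on array 1 and 0.83 on array 2, and the lowest -0.33 and 0.51, while the means of the bins from -450 to -151 bp lay between 0.09 and 0.11. Array 1 had its own lowest upstream bin from -200 bp, at -0.44, and its own highest from 200 bp after the start, at 0.06, and array 2 had its own lowest upstream bin from -450 bp, at 0.45. Around the stop codon the lowest mean was -0.16, from 100 to 149 bp downstream, where array 1 had -0.65 and array 2 had 0.33.

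**Figure D3:**
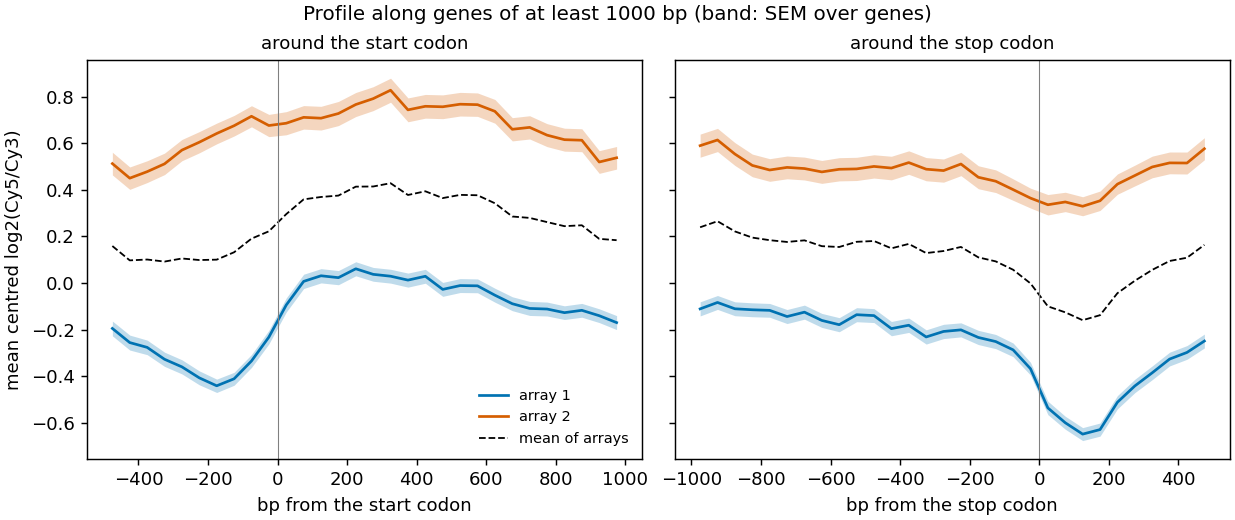
Mean centred log2 ratio per 50 bp bin (y axis) against distance in bp from the start codon (left) and the stop codon (right) for reading frames of at least 1000 bp, with bands of 1 SEM over genes for each array. The mean of the arrays peaks at 0.43 after the start codon and falls to -0.16 after the stop codon, and array 1 dips upstream of the start where array 2 does not.

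Gene groups were compared through 33 lists. Splicing factors had the lowest unadjusted camera p (0.041), with a mean log2 ratio lower than that of other genes by -0.54 on array 1 and -0.57 on array 2, but the adjusted p was 0.983 (adjusted p = 0.99 with an estimated correlation). Splicing factors differed from other genes by -0.25 and -0.26 in Cy5 and by 0.29 and 0.31 in Cy3. The lower ratio therefore came partly from a higher untagged signal. In promoter windows the ratio of this list lay 0.24 above that of other genes (camera adjusted p = 0.823). Of 45 splicing factors 0 passed over all genes and 3 did when adjusted over the list alone. An unadjusted limma p under 0.05 was found in 9 of these 45 genes and in 1114 of all 5480. With so large a share over all genes, members that pass over a list alone do not set that list apart. Their highest members were SNU114 with 3.25 ± 3.23 and SNU13 with 2.89 ± 3.01, and the lowest was PRP8, the core spliceosomal protein, with -3.31 ± 0.56. The median of this list lay at the 0.53 percentile of 10000 random lists.

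No list of the translation machinery passed in the plain ratio. The 129 cytosolic ribosomal protein genes differed from other genes by -0.09 on array 1 and 0.58 on array 2, and 0 of them passed over all genes or adjusted over the list alone. With the fitted slope on the control, chosen after the data were examined, this list passed with a shift of 0.84 (camera adjusted p = 1.9e-06 at the preset correlation). A slope under 1 leaves in part of the Cy3 signal, which was itself higher at these genes, by 0.95 and 1.23. The higher value with the slope is therefore fixed by construction and decides nothing on Sas3-HA. RPP1A, a stalk protein of the large subunit, had the highest plain ratio among the ribosomal protein genes, 3.41 ± 3.59, followed by RPL5 with 3.29 ± 1.21. RPL21A had the lowest, -2.63 ± 0.22. In ribosome biogenesis 94 genes were measured, and UTP15 was higher and RRP36 lower, the latter with -4.17 ± 0.92, while 4 passed when adjusted over the list alone. MPP10 with 3.74 ± 2.86 followed UTP15 as the highest. Translation factors had 1 of 26 members lower, the initiation factor gene TIF4632 with -4.17 ± 0.00, and 2 passed when adjusted over the list alone. The highest translation factor genes were TIF34 with 2.11 ± 1.53 and TIF3 with 1.94 ± 0.46. No aminoacyl-tRNA synthetase gene passed among 20 measured, of which FRS2 had the highest mean, 3.06 ± 2.74, followed by YDR341C with 2.65 ± 2.41, and ALA1 the lowest, -2.71 ± 0.04.

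No list of metabolic genes passed in the plain ratio. The 20 genes of glycolysis and fermentation differed from other genes by 0.25 and 0.52 on the arrays, with 0 members passing, and their highest mean was 2.89 ± 1.99 at FBA1, the aldolase gene, followed by GPM1 with 2.13 ± 1.78, while HXK1 had the lowest, -2.23 ± 0.10. With the fitted slope on the control, this list passed with a shift of 0.91 (camera adjusted p = 0.022 at the preset correlation). As for the ribosomal protein list, Cy3 was itself higher at these genes, by 0.74 and 1.19, so that pass decides nothing on Sas3-HA. Amino acid biosynthesis genes differed by 0.33 and 0.25, with 0 of 64 members passing, and GDH1 with 2.96 ± 2.61 and ASN2 with 2.75 ± 2.01 were the highest and MET14 with -1.79 ± 1.83 the lowest. Among 38 nuclear genes of the respiratory chain and ATP synthase, COX7 was higher with 3.95 ± 3.89, and among 63 mitochondrial ribosomal protein genes MRP13 was lower with -3.81 ± 0.65, while 2 and 6 members passed when adjusted over each list alone. After COX7 came CYT1 with 2.95 ± 1.70, and COX4 was the lowest of its list with -3.49 ± 1.20. The highest mitochondrial ribosomal protein genes were MRP51 with 3.54 ± 3.18 and MRPL33 with 3.50 ± 3.08. In the TCA cycle, ergosterol and phosphate lists 0 members passed, with 20, 24 and 15 genes measured, and adjusted over the list alone 3 ergosterol genes passed.

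Among genes induced by stress, sporulation or mating, HSP12, a membrane-associated stress protein, was lower with -3.89 ± 0.35. Of 41 stress genes 6 passed when adjusted over the list alone, and 9 had an unadjusted limma p under 0.05, a share near that of all genes. The highest stress genes were TSL1 with 3.52 ± 3.51 and GAD1 with 3.51 ± 1.70. SPS100, a spore wall gene, was higher with 4.05 ± 2.54, the single call among 62 meiosis and sporulation genes, of which 2 passed when adjusted over the list alone. AMA1 followed with 2.55 ± 3.23, and MEI5 was the lowest with -3.40 ± 0.35. Of the pheromone, a-specific, alpha-specific and galactose lists, none had a member that passed over all genes, and adjusted over the list alone 1 a-specific gene did. Cell cycle genes included 2 lower members among 30 in the list of mitotic and early G1 genes, of which MCM5 was the lowest, and 4 passed when adjusted over the list alone. MCM7 and SCW11 were the highest of that list with 3.07 ± 2.71 and 2.63 ± 1.42. Among 22 plasma membrane transporter genes TAT2, an amino acid permease, was higher with 3.90 ± 2.25, and 3 passed when adjusted over the list alone. LYP1 with 2.98 ± 3.34 was next, and ITR1 with -3.29 ± 0.12 the lowest. Of 32 proteasome genes PUP2 was the single call, with 3 when adjusted over the list alone, RPN11 was next with 3.46 ± 1.36, and PRE2 was the lowest with -3.16 ± 0.88. No member passed among 33 chaperone, 47 cell wall, 32 G1/S, 28 autophagy, 41 secretory pathway, 23 subtelomeric and 6 seripauperin and cold-shock genes, and adjusted over the list alone 2 chaperone and 2 G1/S genes did.

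In chromatin and transcription, 0 of 31 SAGA and NuA4 subunit genes passed, with TAF10 highest at 2.81 ± 0.66, UBP8 next at 2.68 ± 1.92 and TAF9 lowest at -2.42 ± 0.65. Of 20 genes for regulators of histone H3 methylation 0 passed and 1 did when adjusted over the list alone, with CTR9 and PAF1 highest at 2.32 ± 0.20 and 2.22 ± 2.42 and BRE2 lowest at -3.57 ± 0.43. RPA14 was the lower member among 31 RNA polymerase subunit genes, of which 3 passed when adjusted over the list alone, and RPA12 and RPC37 were the highest with 3.31 ± 2.14 and 2.77 ± 1.96. Core histone genes, with 6 measured, had means from -1.28 ± 1.24 at HTA1 to 0.72 ± 1.45 at HTB2, with HHT2 next at 0.49 ± 2.40. By camera 0 of 33 lists passed, with 1 at an unadjusted p under 0.05, and with an estimated correlation also 0.

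**Figure D4:**
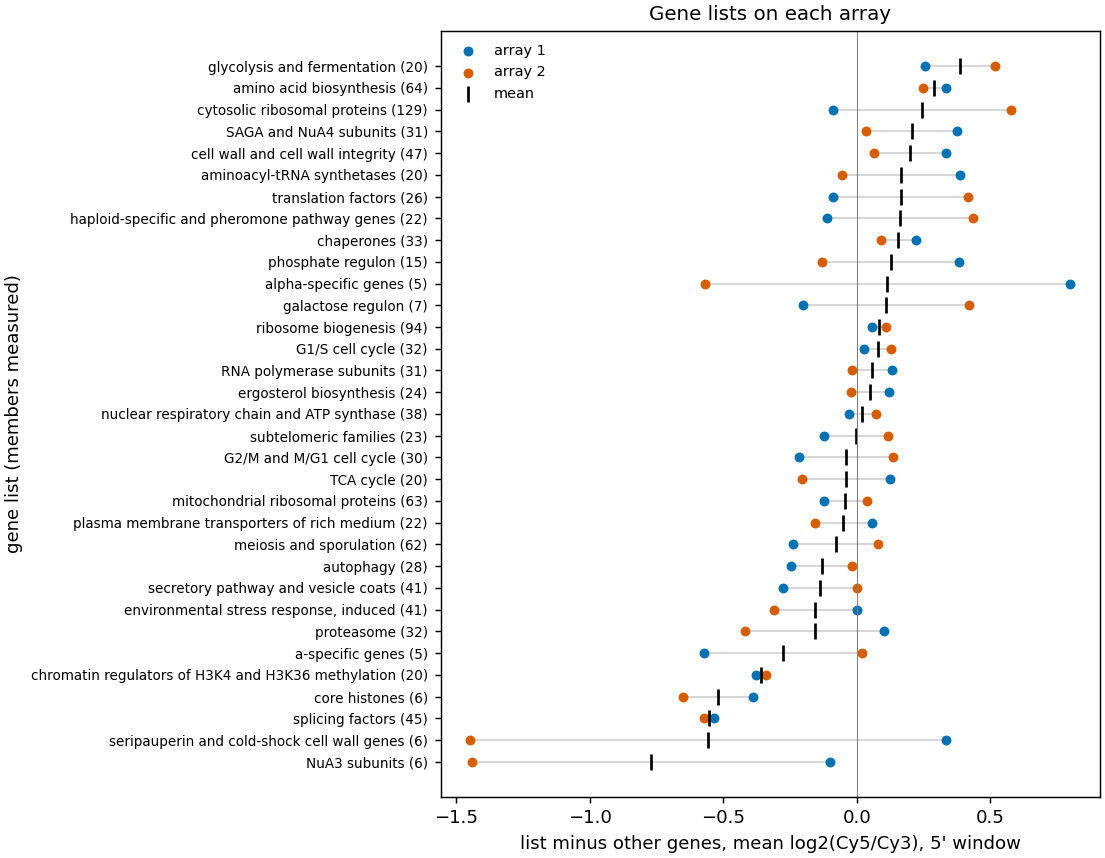
Mean log2 ratio of each of 33 gene lists minus that of all other genes in the 5' window (x axis), for array 1, array 2 and their mean, with the number of members measured in parentheses. Splicing factors lie at -0.54 and -0.57, and the ribosomal protein list at -0.09 on array 1 and 0.58 on array 2.

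Outside reading frames, intergenic intervals between convergent genes had the lowest median among the larger intergenic classes, -0.24 over 1082 intervals, against 0.13 for circular shifts (adjusted permutation p = 0.008). Shifted values come mostly from reading frames, which hold 73.1% of nuclear probes. A low p against shifts therefore does not set a class apart from other intergenic sequence. Tandem intergenic intervals had 0.03 over 2428 intervals (adjusted permutation p = 0.008), intervals with a tRNA gene -0.07 over 247 (adjusted permutation p = 0.008), and subtelomeric tiles -0.07 over 496 (adjusted permutation p = 0.016). Divergent promoters, with 0.18 over 1322 intervals, did not pass against shifted values (adjusted permutation p = 0.469), nor did the mitochondrial, snoRNA and snRNA classes. These calls came from array 1: on array 2 alone 0 of 8 classes passed, and the tandem median, 0.33, lay above its shifted value of 0.31. On that array convergent intervals had 0.05 against 0.23, tRNA intervals 0.42 against 0.48 and subtelomeric tiles 0.28 against 0.43, below their shifted values as on array 1. Intervals with a tRNA gene did not pass against other intergenic intervals when interval labels were permuted, with a difference of -0.08 (permutation p = 0.478, adjusted p = 0.479), a test chosen after the data were examined.

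**Figure D5:**
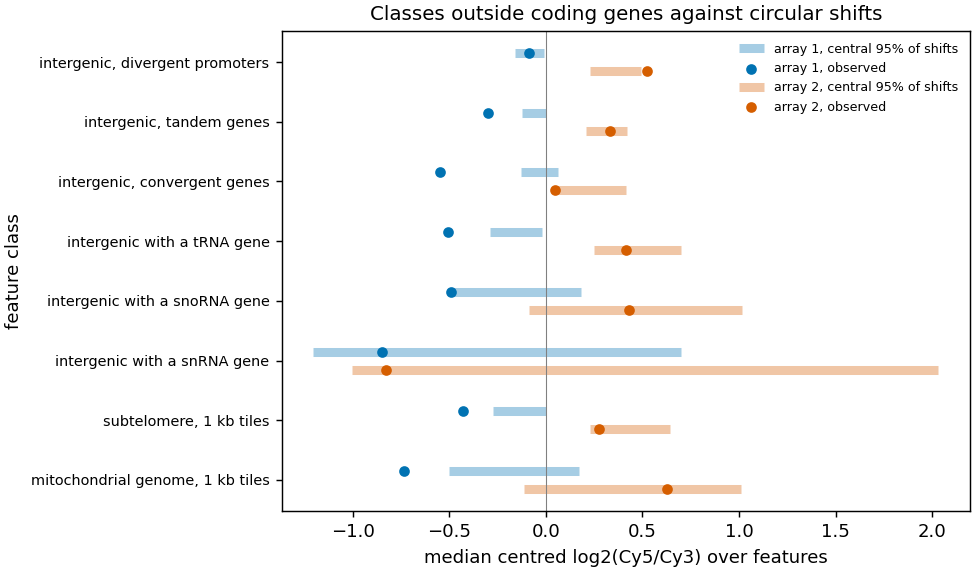
Median centred log2 ratio over the features of each class (x axis) on array 1 and array 2, with bars for the central 95% of 1000 circular shifts. On array 1 convergent intervals lie at -0.55 outside their bar, and on array 2 at 0.05 within it.

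A single run of probes passed the enrichment threshold on both arrays. It covers 703003 to 703193 on chromosome 2, inside the reading frame of VVS1, with a mean of 6.90 ± 2.64 (SD, n = 2) over 5 probes. With the same cut-offs below the centre 87 runs were depleted, with a median length of 281 bp. Of these, 78.2% lay mainly inside reading frames, as did 73.1% of nuclear probes. The most negative, chosen after its values were seen, lies at 189916 to 190298 on chromosome 5 within AFG3, the gene of a mitochondrial protease subunit, with -6.16 ± 0.77. Both counts rest on the threshold: at 1.5 robust SD 12 runs were enriched and 489 depleted, and at 3 robust SD 0 and 1. The robust SD, from values below the centre alone, was 1.97 on array 1 and 1.95 on array 2. Over all probes the SD was 1.64 and 2.63, so values above the centre spread less on array 1 and more on array 2. The numbers of enriched and depleted runs therefore cannot be set against each other.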

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

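The fitted slope on the control channel and the equal scaling of the arrays were chosen after the data were examined, and the other settings before. No paired analysis was possible because the arrays form a single group. Correction for probe GC content, probes with several matches and windows of 100 or 250 bp around non-coding features were not run, since no probe or genome sequence was used. The series value table gave the same values as the scanner files by construction. With 2 arrays a mean lies closer than 1 SD to either array, so leaving out an array says nothing on the stability of means, and it leaves no test per gene. Signal over background was lowest for Cy5 on array 2, with a median of 12.8 against 141 on array 1. The trend of the variance was fitted on the mean ratio, the value tested, so counts with trend and robust variance decide nothing on direction. Unless stated, the cause of a change was not tested.

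Counts of genes in the 5' window, 61 as reported, became 355 with normexp, 293 with loess, 371 with mean centring, 376 without centring, 115 with dim probes left out, 21 with flagged spots kept, 2 with the fitted slope (DMA2 and PUP2), 431 with equal scaling, 120 with medians over probes, 128 with at least 5 probes, 140 with windows of 250 bp, 206 with windows of 1000 bp, 307 with trend and robust variance, 39 without genes near chromosome ends, 0 without moderation and 5 with treat against 0.5. All 61 genes were among those called with normexp, loess, either centring or equal scaling. Promoter counts, 0 as reported, were 242 with loess, 326 with mean centring, 313 without centring and 152 with equal scaling. With trend and robust variance 344 passed, all of them lower. For 3' windows, 163 as reported, they were 275 with normexp, 261 with loess, 308 with mean centring, 314 without centring, 0 with the fitted slope, 285 with equal scaling (117 higher and 168 lower), 102 with medians and 412 with trend and robust variance, all of those 412 lower.

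For 5' minus 3', 243 as reported, counts were 0 with normexp, loess, the fitted slope, or trend and robust variance, 161 with medians, 102 with windows of 1000 bp (1245 genes tested) and 39 among genes with no neighbour within 500 bp (495 genes tested). The mean over genes was 0.23 with the fitted slope and 0.32 among genes with no such neighbour, and 0.24 to 0.27 on the single arrays. For 5' minus promoter, 282 as reported, counts were 3 with the fitted slope (JEN1, LYP1 and PAT1), 442 with equal scaling, 20 with medians, 101 with windows of 250 bp, 0 with trend and robust variance and 30 among genes with no near neighbour (781 genes tested), and the mean was 0.50 with the fitted slope and 0.11 to 0.31 on the single arrays. Gene lists called were 2 with the fitted slope and 0 in the other camera runs, and 1 list, splicing factors, lay outside the central 95% of random lists. Ratio agreement was 0.23 with the fitted slope.

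On the single arrays 0 to 6 feature classes passed. Medians ranged from -0.30 to 0.33 for tandem intervals, which turned direction against shifted values on array 2, from -0.547 to 0.0483 for convergent intervals, from -0.51 to 0.42 for tRNA intervals, from -0.43 to 0.28 for subtelomeres, from -0.49 to 0.43 for snoRNA intervals and from -0.74 to 0.63 for the mitochondrial genome. Shifted values moved with the arrays too, from -0.03 to 0.23, from -0.16 to 0.48 and from -0.13 to 0.43 for convergent intervals, tRNA intervals and subtelomeres, which lay below them on both arrays. SnoRNA intervals and the mitochondrial genome passed on array 1 alone. Enriched runs numbered 12 at 1.5 robust SD, 0 at 3, 4 with at least 3 probes and 0 with at least 8, and depleted runs, 87 as reported, numbered 489, 1, 247 and 21. Of the named genes' values under other settings, 457 kept their side of the threshold, 94 lost it, 26 gained it (all in promoter windows) and 0 changed direction. These genes were chosen for extreme means of the same sign on the same arrays, so the lack of a change in direction decides nothing. Sizes did change: the weakest values of the 12 higher 5' window genes ran from 1.68 (DMA2) to 4.00 (PUP2). Those of the 8 lower ones ran from -2.24 (SSK1) to -1.33 (MCM5).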

Other observations

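The covariances of the channels, the correlations between probes, the list shifts in single channels, the circular shifts and the fitted slope were tests chosen only after the result was seen, whereas the loess run and the list tests in the plain ratio were planned.

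Several gene lists, ribosomal protein and glycolysis genes among them, had higher mean signals than other genes in both precipitates. No p-value was computed for these shifts in single channels. In Cy5 the 129 ribosomal protein genes exceeded other genes by 0.86 on array 1 and 1.81 on array 2 in the 5' window, and in Cy3, from cells without an HA tag, by 0.95 and 1.23. Glycolysis and fermentation genes exceeded others by 1.00 and 1.71 in Cy5 and by 0.74 and 1.19 in Cy3. Core histone genes, with 6 measured, exceeded others by 0.96 and 1.30 in Cy5 and by 1.35 and 1.95 in Cy3, and 22 plasma membrane transporter genes by 0.80 and 0.96 in Cy5 and by 0.74 and 1.12 in Cy3. Mitochondrial ribosomal protein genes differed by at most 0.13 in either channel. Other lists lay below other genes in both channels. Meiosis and sporulation genes differed by -0.83 and -0.57 in Cy5 and by -0.59 and -0.65 in Cy3. Subtelomeric families differed by -0.58 and -0.39 in Cy5 and by -0.46 and -0.51 in Cy3.

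When the control was subtracted with its fitted slope, 0.39 on array 1 and 0.51 on array 2, the ribosomal protein list stood 0.84 above other genes (camera adjusted p = 1.9e-06) and the glycolysis list 0.91 (adjusted p = 0.022), whereas neither passed in the plain ratio. Control signal left in by a slope under 1 and more Sas3-HA at these genes cannot be told apart here. The shift with the slope equals the plain shift plus the part of the Cy3 shift that was not subtracted, and the smallest Cy3 shift of either list on either array was 0.74, so the higher value with the slope is fixed by construction and decides nothing. The plain-ratio shift of the ribosomal protein list was -0.0886 on array 1 and 0.58 on array 2.

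The ratios of the arrays correlated more than their Cy5 signals did. The covariance of the 5' window ratios between arrays was 1.40. The part specific to Cy3 was 1.44 and the part specific to Cy5 -0.0358. That Cy5 part is the Cy5 covariance, 0.39, minus the mean of unequal covariances across channels, 0.24 and 0.61. With both Cy3 profiles fitted out, the Cy5 signals still correlated with r = 0.23 between arrays. Control structure may account for the agreement of the ratios, but the Cy5 signals also share some structure not carried by Cy3. Independent spot noise in Cy5 is argued against, since the Cy5 difference between arrays correlated with r = 0.90 between probes 50 bp apart. Amplification of different fragments in the Cy5 samples cannot be told apart from cultures that differed in binding: the correlation was 0.75 at 100 bp and 0.01 at 1000 bp, which either would give. No biological explanation was tested.

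The mean ratio was higher at the 5' than at the 3' end of genes on both arrays. It is an average over genes that varied widely, as 56.2% on array 1 and 52.6% on array 2 had a difference above 0. Dye bias that follows intensity is argued against as the whole cause, since the mean difference was 0.26 after loess, outside the range of circular shifts on each array. A slope of the control channel alone is argued against too, since Cy5 by itself had a mean difference of at least 0.19 on each array, also outside that range. Base composition was not tested, and Sas3 lying nearer to gene starts stays open as an untested biological explanation, because dye and sample were not swapped.

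Spacing of the signal along the genome was short in every channel. The correlation between probes 400 bp apart was 0.13 and 0.12 for Cy5 and 0.17 and 0.15 for Cy3 on arrays 1 and 2.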
